A study of Mus musculus with 36 samples.

How the data were processed

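The series holds 36 samples from crypts of the mouse small intestine. Immunoprecipitations for 8 marks and an input were made from each of 4 pools, fed pools 1 and 4 and fasted pools 2 and 5, with the crypts of 4 animals in a pool, per the labels. Animals of both sexes were pooled, and the histone deacetylase inhibitor trichostatin A was present during crypt isolation, per the labels' protocols. The design text of the series speaks of 9 modifications, whereas the labels name 8 antibodies and the input. The 4 input samples had no list of their own and entered no comparison. Groups and replicate numbers were taken from the labels. Replicates are separate pools, so the exact permutation p-values measure the spread between pools. Fisher and binomial p-values run over regions or lists and do not.

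The deposited files are peak lists with 5 columns: chromosome, start, end, a peak name and a score. The score is the authors' peak caller value, -10 times the log10 of p, and its lowest value in the deposited lists is 50, or p = 1e-05. Peaks were called in each library against the input of the same pool with MACS 1 and without model building, per the file names. The submitters' processing notes name FastQC, Bowtie 1.1.2, SAMtools 1.9 and deepTools 1.5.11 and the mm9 build. Other filters and the read depths are not given in the sources used here. Because every list was called on its own, the number and the width of peaks move with depth, antibody yield and input as well as with the mark. Score was used only to rank or filter peaks within a list.

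Intervals were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plotted with matplotlib 3.10.9. Peaks of the 4 libraries of a mark were merged where they overlapped or touched, and a library was taken to call a merged region when 1 of its peaks overlapped it by 1 bp or more. A region called in both fasted and in no fed library was termed fasted-only, and the reverse fed-only. Peak numbers, covered lengths and shares of peaks with another mark were compared by two-sided exact permutation tests over the 4 libraries, with Benjamini-Hochberg adjustment over the 8 marks for number and length. Ratios carry an SD propagated from the SDs of both conditions. Shares of H3K9bhb or H4K12bhb peaks with another mark used an overlap of 1 bp with the mark of the same pool, beside the mean of 200 circular shifts of the peaks within chromosomes. Their Wilson 95% intervals cover counting error only. Odds ratios compared fasted-only with all other merged H3K9bhb regions, with 0.5 added to each cell and a 95% percentile interval from 1000 resamples of the 21 chromosomes. Enhancer-like regions had no H3K4me3 peak and had an H3K4me1 or H3K27ac peak in any library. The named regions were the 10 fasted-only and the 10 fed-only H3K9bhb regions with the highest value of the lower of their 2 score percentiles, a rule set before the data were examined, as were the comparisons of peak number, length, overlap, shares, odds ratios and mark classes. The long domains, regions with both H3K4me3 and H3K27me3, regions without H3K27ac, chromosome X and the tests of explanations were chosen later. Positions are given counted from 1.

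The interval functions gave the same values as bedtools 2.31.1 in 4 of 4 checks on the deposited lists. On simulated data with 30000 sites, 2000 of 2000 planted fasted-only regions were recovered. A planted H3K27ac odds ratio of 3 was estimated as 3.14, and the interval held the planted value in 94 of 100 simulated sets. The simulated planted regions were in both fasted lists and the other sites in all 4 H3K9bhb lists, so full recovery checks the code only. Simulated sites were independent of each other and had no calling threshold. Unequal sensitivity of the lists and dependence along chromosomes were therefore not covered.

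Alternatives fixed in advance were a score of 100 or more, equal numbers of top-scoring peaks per library of a mark, merging across gaps of up to 1000 bp, 50% of a region or peak covered, removal of regions with H3K9me3, each library left out, and comparison within each run of the file names. Alternatives chosen after seeing the data counted the other mark in any pool, used equal numbers for H3K9bhb alone, and gave odds ratios and classes within runs. The gene reference used here was on another build than mm9, so its positions were not used with the files. Gene lists, cell type markers and distances to transcription starts were therefore not analysed here, and regions are named by position.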

Results

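Histone modifications were mapped by chromatin immunoprecipitation and sequencing in crypts of the mouse small intestine, from animals with free access to food and from animals deprived of food for 24 h. Each replicate pooled the crypts of 4 animals, so a replicate is a pool and not a single mouse. Fed pools 1 and 4 and fasted pools 2 and 5 were each profiled for 8 marks, which gave 32 peak lists with 2 libraries per mark and condition. H3K9bhb and H4K12bhb are lysine β-hydroxybutyrylation marks, whose acyl group comes from the ketone body β-hydroxybutyrate. H3K27ac lies at active promoters and enhancers, H3K4me1 at enhancers, H3K4me3 at promoters and H3K79me2 over transcribed genes. H3K27me3 is the Polycomb mark and H3K9me3 marks heterochromatin. The lists held from 59 to 46499 peaks. The read depth behind them is unknown, because a peak list carries no read totals. All positions are on the mm9 build of the mouse genome and no gene names were attached to them.

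The series asks how fasting changes the distribution of H3K9bhb. Many more H3K9bhb peaks were called in fasted than in fed crypts. Fed pools 1 and 4 gave 19555 and 13923 peaks, a mean of 16739 ± 3982 (SD, n = 2), and fasted pools 2 and 5 gave 38934 and 37640, a mean of 38287 ± 915 (SD, n = 2). The ratio of fasted to fed means was 2.29 with an SD of 0.55, and the shorter fasted list was 1.92 times as long as the longer fed list. H3K9bhb peaks were also wider after fasting, with mean lengths of 2127 and 2282 bp against 1529 and 1593 bp. They covered 84.4 ± 2.2 Mb in fasted and 26.0 ± 5.5 Mb in fed crypts (SD, n = 2 each), a ratio of 3.24 with an SD of 0.69. The difference between conditions exceeded the spread between pools, but with 2 libraries against 2 a two-sided exact permutation test cannot go below p = 0.33, the value obtained for both number and length. The file names place fed pool 1 with fasted pool 2 in run 10 and fed pool 4 with fasted pool 5 in run 11, and the peak number ratio was 1.99 and 2.70 within these runs. Among peaks with a score of 100 or more the ratio was 3.84. Median scores were lower in the fed lists (77.0 and 78.3) than in the fasted lists (98.7 and 110.6). A fixed score therefore removed a larger part of the fed lists and is no independent check.

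**Figure D1:**
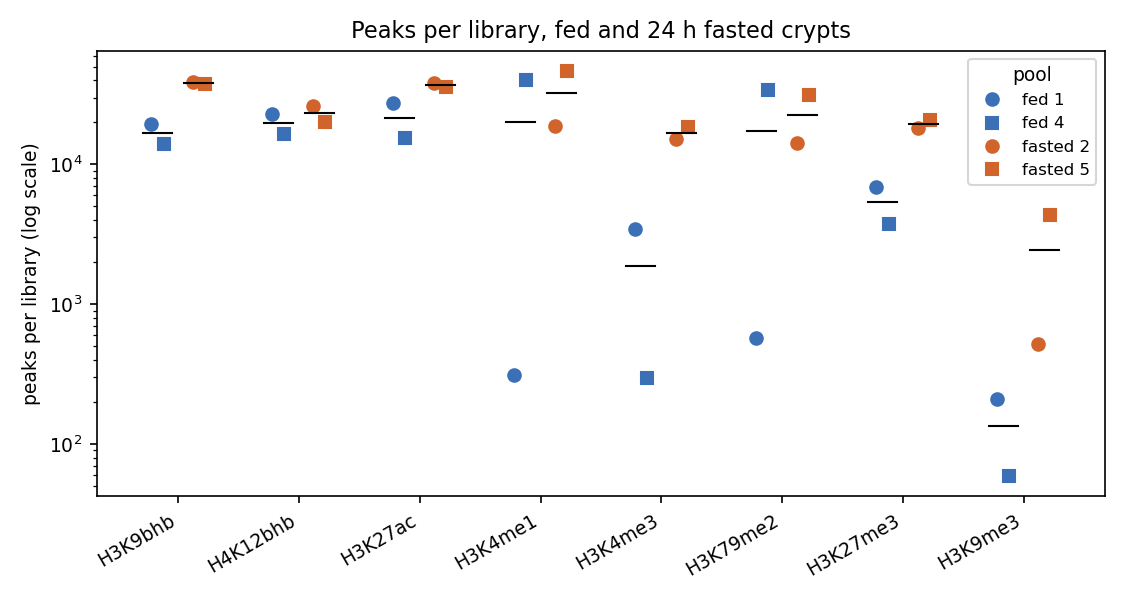
Number of peaks per library (log axis) for each of the 8 marks, with fed pools in blue, fasted pools in orange, circles for pools 1 and 2, squares for pools 4 and 5, and black lines for the mean of the 2 pools. For H3K9bhb the fasted pools lie at 38934 and 37640 peaks, above the fed pools at 19555 and 13923, whereas for H4K12bhb the conditions overlap.

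The second β-hydroxybutyryl mark differed less between conditions. H4K12bhb gave 23073 and 16560 peaks in the fed pools and 26252 and 20031 in the fasted pools, a ratio of 1.17 with an SD of 0.35, so the conditions overlapped. Within runs 10 and 11 the fasted list was the longer each time, with ratios of 1.14 and 1.21. H3K27ac rose from a fed mean of 21572 ± 8581 to a fasted mean of 36946 ± 1455 (SD, n = 2 each), a ratio of 1.71 with an SD of 0.68. H3K27me3 gave 6914 and 3760 peaks in fed and 18259 and 20887 in fasted pools, a ratio of 3.67 with an SD of 1.57. H3K4me3 gave 3430 and 295 peaks in fed and 15079 and 18429 in fasted pools, and H3K9me3 gave 208 and 59 against 521 and 4376, a ratio of 18.3 with an SD of 25.03 that was 3.90 without fasted pool 5 and 41.5 without fed pool 1. For H3K4me1 and H3K79me2 both lists of run 11 were long, fed pool 1 had the fewest peaks and fasted pool 2 lay between. H3K4me1 gave 309 and 18692 peaks in fed pool 1 and fasted pool 2 of run 10, and 39865 and 46499 in fed pool 4 and fasted pool 5 of run 11. H3K79me2 gave 571 and 14129 in run 10 and 33841 and 31246 in run 11, and the pools of run 11 shared the most, with a base-pair Jaccard index, the shared length over the joint length, of 0.499 and 0.643. Both fasted lists exceeded both fed lists for 5 of the 8 marks, H3K9bhb among them, each with an exact permutation p of 0.33 and a Benjamini-Hochberg adjusted value of 0.533 over the 8 marks. The H3K4me1 and H3K79me2 ratios were 1.62 and 1.32 with all pools and 0.818 and 0.670 without fed pool 1, so the direction turned when that library was left out, and leaving out fasted pool 5 gave 0.931 and 0.821. Without fed pool 4 they were 105 and 39.7, and the H3K4me3 ratio of 9.00 became 4.88 without fed pool 4 and 56.8 without fed pool 1.

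The H3K9bhb peaks of the fasted pools resembled each other far more than those of the fed pools did. For H3K9bhb the Jaccard index was 0.532 between the fasted pools and 0.265 between the fed pools. Pairs of a fed and a fasted pool lay between 0.213 and 0.260, so the fed pair barely exceeded the pairs across conditions. Most peaks of a fed pool nevertheless met a peak of a fasted pool: 78.7% of those of fed pool 1 and 85.9% of those of fed pool 4 overlapped fasted pool 2. With equal numbers of top-scoring peaks, 13923 per library, the fed pair stood at 0.269, below the 0.271 to 0.288 of the pairs across conditions, and the fasted pair at 0.527. For H3K27ac the index was 0.650 between fasted and 0.254 between fed pools. H4K12bhb did not: its highest index, 0.518, joined fed pool 1 and fasted pool 2, above 0.469 between the fasted and 0.427 between the fed pools.

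H3K9bhb regions called only in both fasted pools were numerous and those called only in both fed pools were rare. The peaks of the 4 libraries merged into 45974 H3K9bhb regions, of which 8645 (18.8%) were called in both fasted pools and in neither fed pool. Only 95 were called in both fed pools and in neither fasted pool, 5186 were called in all 4, and the other patterns of exactly 2 libraries held 369 to 832 regions. H3K27ac gave a like picture, with 8313 fasted-only and 127 fed-only regions among 43071. H4K12bhb had 1644 fasted-only and 531 fed-only regions among 29874, fewer than the 2110 regions called only in fed pool 1 and fasted pool 2. Fasted-only regions numbered 9120 for H3K4me3, 5350 for H3K27me3, 1268 for H3K4me1, 190 for H3K79me2 and 133 for H3K9me3, while 13897 H3K4me1 and 10988 H3K79me2 regions were called only in the pools of run 11. Leaving out 1 library, so that fewer lists had to match, gave 10755 to 22931 fasted-only and 299 to 2559 fed-only H3K9bhb regions. In the same way the fasted-only counts became 2072 to 8806 for H4K12bhb, 9630 to 18335 for H3K27ac, 9259 to 15154 for H3K4me3, 5855 to 16858 for H3K27me3, 1275 to 17340 for H3K4me1, 199 to 7074 for H3K79me2 and 135 to 4303 for H3K9me3. The same number of top-scoring peaks from each library, 13923 for H3K9bhb, gave 1788 fasted-only and 333 fed-only H3K9bhb regions, with 390 to 589 in the remaining 4 patterns. In that setting H3K27ac had 2829 fasted-only regions and at most 382 in any other pattern, and H4K12bhb had 1161 fasted-only regions against 941 in fed pool 1 with fasted pool 2. No p-value was given, since regions are not replicates.

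**Figure D2:**
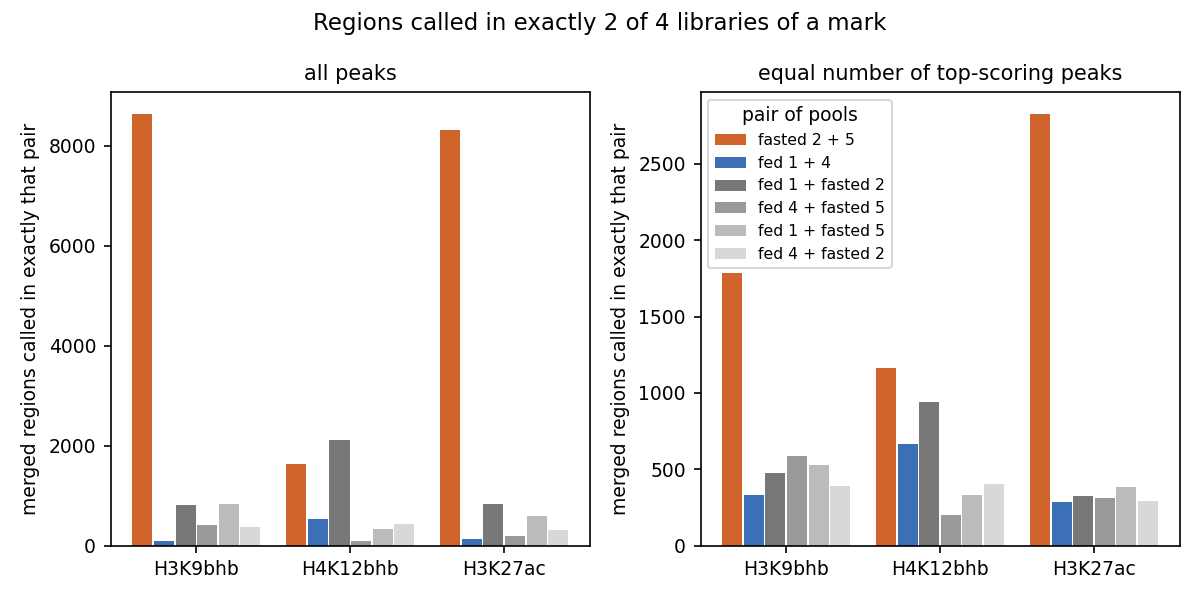
Number of merged regions called in exactly 2 of the 4 libraries of H3K9bhb, H4K12bhb and H3K27ac, with 1 bar for each pair of pools, for all peaks (left) and for equal numbers of top-scoring peaks (right). The pair of fasted pools has 8645 H3K9bhb regions with all peaks and 1788 with equal numbers, the highest of the H3K9bhb bars in both settings, while for H4K12bhb with all peaks the pair of fed pool 1 and fasted pool 2 is highest at 2110.

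The strongest H3K9bhb regions called only in fasted crypts all overlapped an H3K27ac peak of at least 1 fed library. Ranked by the lower of its score percentiles in the 2 fasted lists, the leading region spanned 11368 bp on chromosome 9 (50971864 to 50983231) and stood above 98.3% of peaks in its weaker list. The next lay on chromosome 2 (35525887 to 35538445), chromosome 11 (3880936 to 3885861) and chromosome 9 again (48534920 to 48556751, the longest at 21832 bp). Others lay on chromosomes 2 (132511509 to 132519470), 7 (134815126 to 134819259), 19 (32434186 to 32438836), 10 (85800206 to 85809587), 5 (149804545 to 149812565) and 14 (69926915 to 69945354). All 10 overlapped H3K27ac and H4K12bhb peaks, each called in at least 1 fed library, and 9 overlapped H3K4me1. An overlap of 1 bp sufficed, and of all 8645 fasted-only regions 47.3% had a fed H3K27ac peak and 43.9% a fed H4K12bhb peak. In the leading region the longest H3K27ac peak was 50973613 to 50975789 in fed pool 1 and 50975027 to 50976761 in fed pool 4. In fasted pools 2 and 5 it was 50970966 to 50977984 and 50971828 to 50979321, so H3K27ac covered less of the region in fed pools. At 5 of the 10 regions H3K4me3 was called in both fasted and in no fed pool, and none of the 10 overlapped H3K27me3 or H3K9me3. The fed H3K4me3 lists held only 3430 and 295 peaks. Of all 12324 H3K4me3 regions called in both fasted pools, 9120 were in no fed list, so this absence was common. The chromosome 14 region was the only one of the 10 with an H3K4me1 peak in fed pool 1, whose list held 309 peaks. Near it lay the longest peaks of unlike marks in fed lists. In fed pool 1 these were H3K9bhb (69898140 to 69913813), H3K4me1 (69876370 to 69881454) and H3K79me2 (69887285 to 69893379). In fed pool 4 it was H3K27me3 (70004262 to 70012396). Whether this place draws calls whatever the mark was not tested.

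The strongest fed-only regions fell into a few places. Of the 10 ranked the same way, 3 lay side by side on chromosome 9 (57797570 to 57809934, 57811449 to 57818342 and 57818527 to 57820889). A further 2 lay on chromosome 14 (26271233 to 26283087 and 26286895 to 26295778) and 2 on chromosome 19 (55923897 to 55927868 and 55934422 to 55940982). The rest were on chromosomes 6 (55274799 to 55278701), 2 (90476428 to 90478256) and 17 (26008811 to 26010704). All 10 overlapped H3K27ac peaks called in a fed and in a fasted library, and 9 overlapped H4K12bhb. Of the 10 regions, 8 lay in 4 domains of merged H3K27ac and H4K12bhb peaks that were 37126 to 50832 bp long, which were looked for after these regions had been seen. On chromosome 9, the domain from 57785800 to 57822925 was covered by H3K9bhb peaks to 79.1% and 75.3% in the fed pools, to 0% in fasted pool 2 and to 14.2% in fasted pool 5. H3K27ac peaks covered 99.0% and 99.6% of it in the fasted pools, whereas the chromosome 14 domain had 0% and 96.9% in fasted and 87.5% and 56.3% in fed pools. H4K12bhb peaks covered 92.7% of the chromosome 9 domain in fasted pool 5 and 0% in fasted pool 2. In H3K9bhb coverage the other 3 domains differed from the chromosome 9 domain. On chromosome 6 H3K9bhb covered 31.2% and 24.9% in the fed pools, 40.6% in fasted pool 2 and 9.86% in fasted pool 5. On chromosome 19 the values were 37.3%, 47.6%, 40.9% and 18.1%, and on chromosome 14 they were 66.6%, 52.8%, 28.9% and 2.60%, in the same order.

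**Figure D3:**
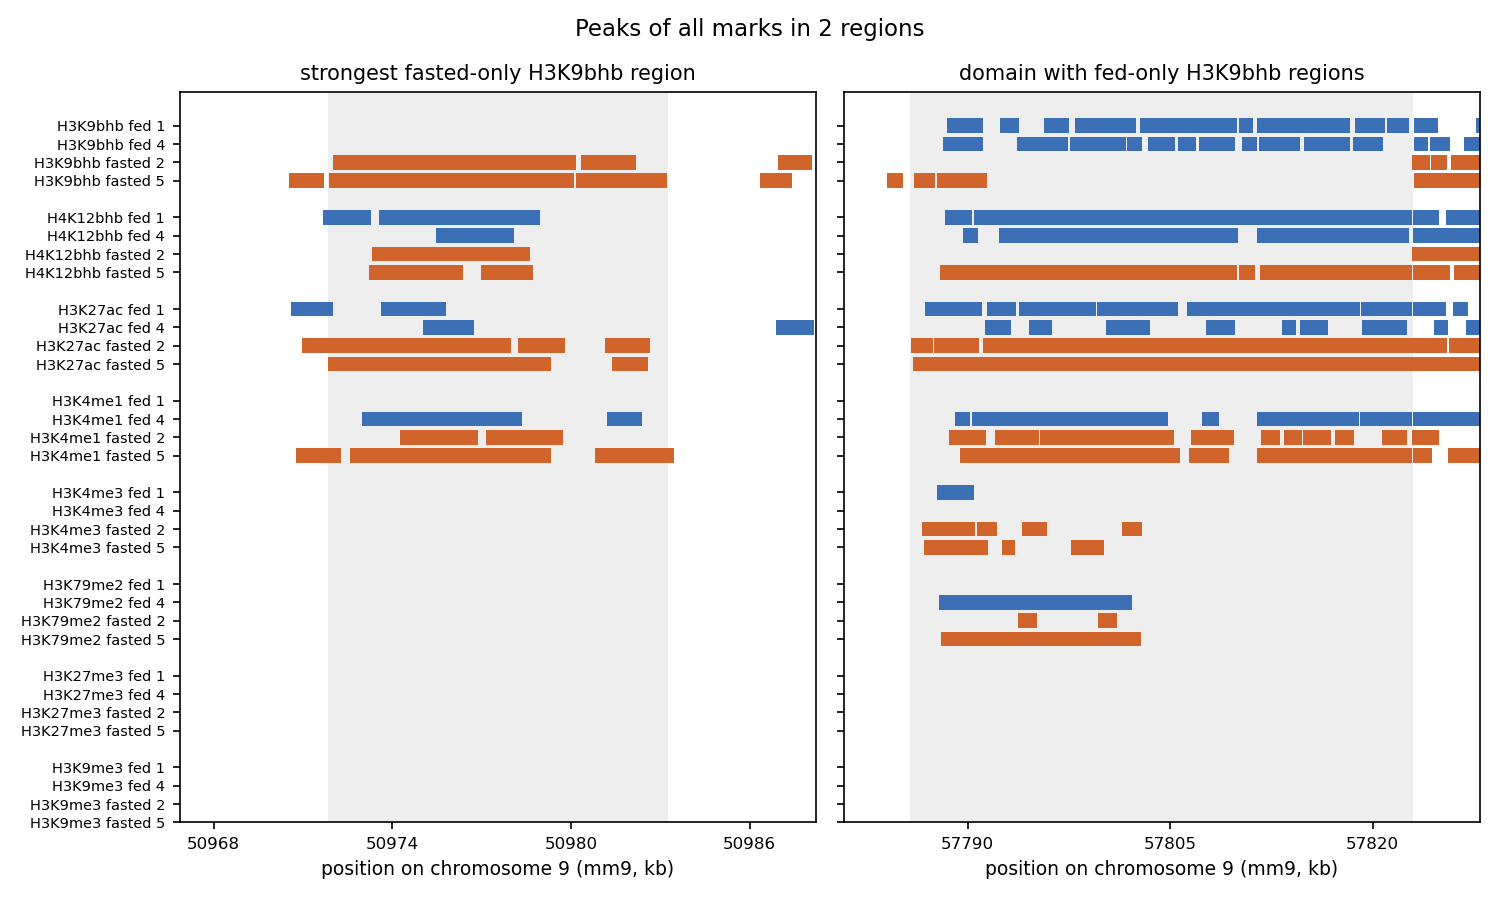
Peaks of all 8 marks in fed (blue) and fasted (orange) pools along chromosome 9 (mm9, kb), with the named region shaded: the leading fasted-only H3K9bhb region (left, 50971864 to 50983231) and a domain holding 3 of the named fed-only regions (right, 57785800 to 57822925). H3K27ac has a peak in every pool at both places but covers less of the left region in the fed pools. H3K9bhb and H4K12bhb of fasted pool 2 have no peak within the right domain.

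H3K9bhb peaks lay mainly in acetylated chromatin and seldom met H3K27me3. In fed crypts 57.4% ± 10.7 of H3K9bhb peaks overlapped H3K27ac of the same pool, and in fasted crypts 72.5% ± 0.45 (SD, n = 2 each). Circular shifts of the peaks gave 3.51% and 1.91% in the fed and 6.40% and 7.01% in the fasted pools. The share was 18.5 and 26.1 times the shifted mean in fed but 11.3 and 10.4 times in fasted pools. Relative to the shifts it was therefore lower in fasted pools. With the higher shifted means there, even an overlap of every fasted peak would have given a lower multiple than in fed pools. The lower multiple therefore does not measure a loss of association. The share with H4K12bhb went down in percent, from 62.3% ± 3.6 in fed to 45.8% ± 12.4 in fasted crypts. The H4K12bhb difference was -7.76 points without fasted pool 5 and -25.4 without fasted pool 2, and the H3K27ac difference was 7.54 without fed pool 4 and 22.7 without fed pool 1. H3K4me3 was met by 8.29% and 1.08% of the fed and 24.1% and 29.5% of the fasted peaks, where the fed H3K4me3 lists held 3430 and 295 peaks. These H3K4me3 shares were 18.7 and 32.1 times the shifted mean in fed and 8.84 and 8.14 times in fasted pools. H3K27me3 was met by at most 0.826% of the peaks of a pool, below the shifted mean of that pool in all 4 pools (0.407% to 3.45%), and H3K9me3 by at most 0.101%. For H3K9me3 the fasted pools lay below the shifted mean, but fed pool 4 did not (0.00718% against 0.00614%), and fed pool 1 had 0.0102% against 0.0194%. Of H4K12bhb peaks, 45.2% ± 2.2 in fed and 78.8% ± 6.2 in fasted crypts overlapped H3K9bhb, and 56.3% ± 12.2 and 89.96% ± 5.50 overlapped H3K27ac (SD, n = 2 each). Relative to the shifted means these shares were lower in fasted pools as well. The H3K9bhb share was 16.1 and 24.5 times that mean in fed and 12.3 and 14.3 times in fasted pools. The H3K27ac share was 16.2 and 24.0 times in fed and 12.7 and 13.7 times in fasted pools. Full overlap in the fasted pools would still have stayed below both fed multiples for H3K27ac, and below that of fed pool 4 for H3K9bhb. These multiples therefore do not measure a loss of association either. For each of the shares in percent the values of the pools did not overlap between conditions, with a two-sided exact permutation p of 0.33, the smallest that 2 pools against 2 allow. The H3K27ac difference at H3K9bhb peaks turned in a setting added after seeing the data: when H3K27ac of any pool counted, 90.9% ± 4.3 of fed and 82.0% ± 1.8 of fasted H3K9bhb peaks met it. In the same setting H4K12bhb peaks met H3K9bhb in 91.0% and 88.3% and H3K27ac in 96.5% and 94.0% of cases, and H3K4me3 at H3K9bhb peaks fell from 38.6% to 29.9%.

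**Figure D4:**
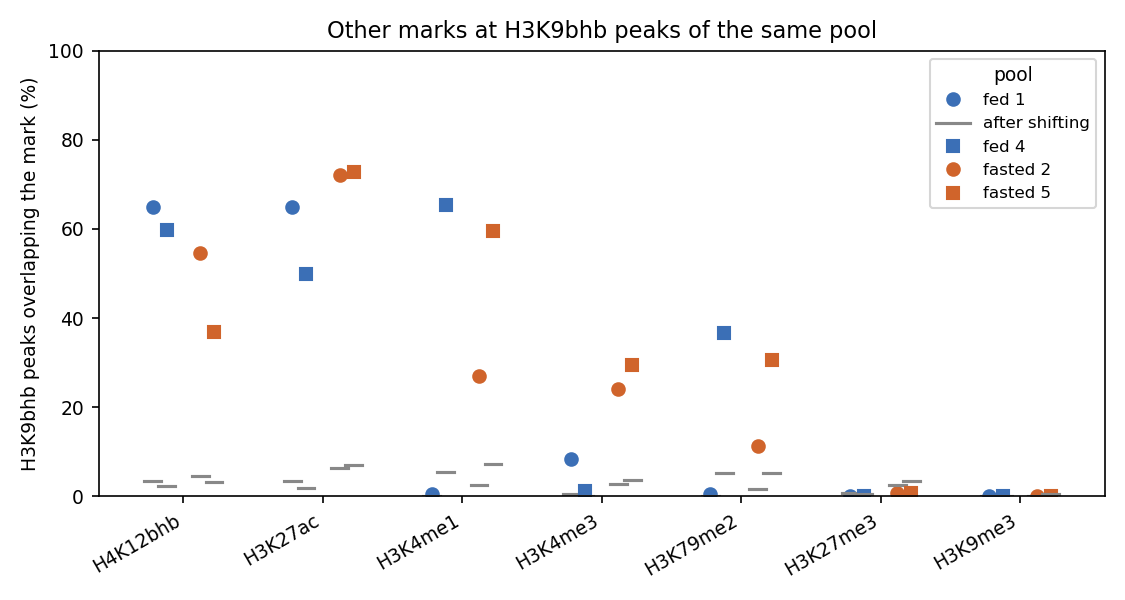
Percent of the H3K9bhb peaks of each pool that overlap a peak of another mark of the same pool, with fed pools in blue, fasted pools in orange, and grey bars for the mean after 200 circular shifts. H3K27ac and H4K12bhb lie far above the shifted values, H3K27ac at 72.2% and 72.8% in the fasted pools, and H3K27me3 lies below them.

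H3K9bhb regions called only in fasted crypts were more often fasted-only for H3K27ac and H4K12bhb than other H3K9bhb regions, though most were not. Of the 8645 fasted-only H3K9bhb regions, 26.8% were also fasted-only for H3K27ac, against 14.98% of the other 37329 H3K9bhb regions, an odds ratio of 2.07 (95% chromosome bootstrap interval 1.95 to 2.20). For H4K12bhb the shares were 6.19% and 2.58%, an odds ratio of 2.49 (2.22 to 2.77). The other mark was often called in fed crypts as well: 47.3% of the fasted-only H3K9bhb regions had an H3K27ac peak in a fed library and 43.9% an H4K12bhb peak. H3K27ac was called at 66.0% of these regions in both fasted pools and at 87.1% in at least 1 of the 4 pools. The odds ratios were 1.31 for H3K4me1 (1.122 to 1.501), 1.18 for H3K4me3 (1.099 to 1.256) and 0.564 for H3K27me3 (0.340 to 0.818). For H3K79me2 and H3K9me3 the intervals held 1. Within runs 10 and 11 the odds ratios were 2.31 and 2.15 for H3K27ac and 2.11 and 1.69 for H4K12bhb, whereas those for H3K4me3 turned to 0.621 and 0.386, those for H3K27me3 to 1.63 and 1.36, and that for H3K4me1 to 0.400 in run 10. The intervals cover variation along the genome in these libraries and not variation between animals.

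The title of the series speaks of enhancers, so H3K9bhb regions were sorted by the marks on them. Regions called only in fasted crypts were mostly enhancer-like, with H3K4me1 or H3K27ac and no H3K4me3 in any library: 62.5% of fasted-only regions against 36.1% of regions called in all 4 libraries. H3K4me3 marked 27.6% of fasted-only and 63.8% of regions called in all 4 libraries. The differences were 26.4 percentage points (24.7 to 27.8) and -36.2 percentage points (-37.7 to -34.3) by chromosome bootstrap, and with 1 library left out the enhancer-like difference was 9.48 to 19.97. Fasted-only regions were also shorter, with a median of 2095 bp against 6450.5 bp, and fed-only regions had a median of 1559 bp. A longer region meets a peak of another mark by 1 bp more easily. Regions were not matched for length or score, so the class differences were not separated from these. Of all H3K9bhb peaks, counted as peaks and not as merged regions, 28.9% and 30.9% in fasted pools 2 and 5 met H3K4me3 of any pool. In fed pools 1 and 4 these shares were 34.8% and 42.4%. The low H3K4me3 share of fasted-only regions was thus close to that of fasted peaks at large. The 95 fed-only regions resembled the fasted-only ones, with 60% enhancer-like and 25.3% H3K4me3-marked, and the intervals of the differences from fasted-only regions, -3.94 to 9.38 and -5.41 to 10.3 percentage points, held 0. The H3K4me3 difference kept its sign within runs 10 and 11 (-21.4 and -28.3 percentage points), but the enhancer-like difference was -4.57 (-5.84 to -3.54) in run 10, 7.61 in run 11 and 0.787 (-1.07 to 2.40) with equal numbers of top-scoring peaks for each mark. It was 23.7 (21.6 to 25.8) when only the H3K9bhb lists were brought to equal numbers.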

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

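The change in H3K79me2 peak number went in opposite directions in the pairs of pools that the file names place in 1 run, which is what singled it out. Fasted pool 2 had 24.7 times as many peaks as fed pool 1 in run 10, and fasted pool 5 had 0.923 times as many as fed pool 4 in run 11. The difference between the runs was not tested, since each holds 1 library per condition. Fed pool 1 gave 571 H3K79me2 peaks and fed pool 4 gave 33841, while the fasted pools gave 14129 and 31246.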

How the results depend on the processing

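No paired analysis was possible because the fed and fasted groups share no replicate numbers in the labels; the runs of the file names served only as a check, with 1 library per condition in each. Of 348 values recomputed under alternatives, 237 stayed within 1 SD of the reported ratio or share, within 1.5 times the reported count, or on the same side of the interval test, and 111 did not. With 2 pools per condition, leaving out 1 pool cannot move a share difference by more than its SD. The same holds for a ratio when a fasted pool is left out. Those values counted among the 237 by construction and are no sign of stability. Where the SD was large, the 237 include values that turned direction. Without fed pool 1 the H3K4me1 peak number ratio was 0.818 against 1.62 as reported (SD 2.46), and that of H3K79me2 0.670 against 1.32 (SD 1.94). The cause was not tested unless the setting itself removes peaks or libraries. The H3K27ac and H4K12bhb odds ratios stayed above 1 in all 11 alternatives (1.57 to 2.93 and 1.69 to 2.97), and the H3K4me3-marked difference stayed negative in 11 of 11 (-37.4 to -9.95). With a score of 100 or more, fasted over fed peak number was 3.84 for H3K9bhb, 3.16 for H3K27ac, 30.5 for H3K4me3 and 7.26 for H3K27me3, and H3K9bhb covered length 5.08. Fasted-only counts were then 378 for H3K4me1, 72 for H3K79me2, 3502 for H3K27me3 and 20 for H3K9me3, and 22 H3K9bhb regions were fed-only. Shares at H3K9bhb peaks then differed by 29.5 points for H3K4me3 and 0.391 for H3K27me3, and at H4K12bhb peaks by 43.9 for H3K9bhb, 48.0 for H3K27ac and 0.328 for H3K27me3. Equal numbers of peaks gave a Jaccard index higher by 0.119 within than between conditions, against 0.162 as reported, and 1788 fasted-only regions for H3K9bhb, 2829 for H3K27ac, 35 for H3K4me1, 65 for H3K4me3, 72 for H3K79me2, 615 for H3K27me3 and 5 for H3K9me3, with 333 fed-only for H3K9bhb. Every list then shrank to the shortest of its mark, 295 peaks for H3K4me3. Odds ratios were then 0.438 for H3K4me1, 0.680 for H3K4me3 and 0.970 for H3K27me3, and the enhancer-like difference was 0.787. Merging across 1000 bp gave 4776 fasted-only and 50 fed-only H3K9bhb regions, 1064 fasted-only for H4K12bhb and 84 for H3K79me2. With 50% of a region covered, fasted-only counts were 13187 for H3K27ac and 82 for H3K9me3. With 50% of a peak covered, shares differed by 0.464 for H3K27me3 at H3K9bhb peaks, and by 41.3 for H3K9bhb and 0.306 for H3K27me3 at H4K12bhb peaks. In run 10 the peak number ratio was 60.5 for H3K4me1 and 24.7 for H3K79me2. Fasted-only counts there were 26420 for H3K9bhb, 9907 for H4K12bhb, 20464 for H3K27ac, 18579 for H3K4me1, 13773 for H3K79me2, 14535 for H3K27me3 and 463 for H3K9me3, with 4160 fed-only for H3K9bhb, since 1 library per condition suffices. In run 11 the ratios were 62.5 for H3K4me3, 5.56 for H3K27me3 and 74.2 for H3K9me3. The counts were 28341 for H3K9bhb, 9226 for H4K12bhb, 26677 for H3K27ac, 17374 for H3K4me1, 18152 for H3K4me3, 6882 for H3K79me2, 18928 for H3K27me3 and 4354 for H3K9me3, with 1870 fed-only for H3K9bhb. The alternatives that follow, up to the libraries left out, were chosen after seeing the data. Odds ratios in run 10 were 0.400 for H3K4me1, 0.621 for H3K4me3, 0.554 for H3K79me2 and 1.63 for H3K27me3, and the enhancer-like difference -4.57. In run 11 they were 0.386 for H3K4me3, 1.21 for H3K79me2 and 1.36 for H3K27me3. Counting the other mark in any pool gave differences at H3K9bhb peaks of -8.91 for H3K27ac, -8.65 for H3K4me3 and 0.572 for H3K27me3, and at H4K12bhb peaks of -2.67 for H3K9bhb, -2.56 for H3K27ac, 0.146 for H3K4me3 and -0.030 for H3K9me3. Equal numbers for H3K9bhb alone gave odds ratios of 1.26 for H3K4me1, 0.587 for H3K27me3 and 3.56 for H3K9me3. Leaving out each library in turn gave peak number ratios of 0.818 to 105 for H3K4me1, 4.88 to 56.8 for H3K4me3 and 0.670 to 39.7 for H3K79me2. Fasted-only counts were 10755 to 22931 for H3K9bhb, 2072 to 8806 for H4K12bhb, 9630 to 18335 for H3K27ac, 1275 to 17340 for H3K4me1, 9259 to 15154 for H3K4me3, 199 to 7074 for H3K79me2, 5855 to 16858 for H3K27me3 and 135 to 4303 for H3K9me3, and fed-only H3K9bhb regions 299 to 2559. Odds ratios were 0.561 to 1.41 for H3K4me3, 0.722 to 1.76 for H3K79me2, 0.565 to 1.87 for H3K27me3 and 0.412 to 4.27 for H3K9me3. Gene list enrichment, the share of regions near transcription starts and cell type markers were not run. Depth, unknown here, limits every peak count.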

Other observations

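The comparisons in this part were chosen after seeing the data. Regions carrying both H3K4me3 and the Polycomb mark H3K27me3 were poor in H3K9bhb and H4K12bhb peaks in fasted crypts. Of 12324 regions with H3K4me3 in both fasted pools, 897 (7.28%) also had H3K27me3 in both and 11090 had it in neither. H3K9bhb was called at 11.7% and 12.4% of the first in fasted pools 2 and 5, and at 63.7% and 68.9% of the second. H4K12bhb was called at 16.7% and 9.59% against 76.7% and 67.6%, and H3K27ac at 25.1% and 41.2% against 91.3% and 97.2%. H3K79me2, a mark of transcribed genes, was called at 1.00% and 5.35% against 24.0% and 63.2%. The Wilson intervals of the paired shares did not overlap in either pool for any of these 4 marks.

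Some H3K9bhb regions of either condition lay outside H3K27ac. No H3K27ac peak of any pool overlapped 1119 of the 8645 fasted-only regions (12.9%) and 17 of the 95 fed-only regions (17.9%), against 7 of the 5186 regions called in all 4 libraries (0.135%). Of the 1119 fasted-only regions, 23.6% overlapped H3K4me1, 19.7% H3K79me2, 17.8% H4K12bhb and 1.70% H3K27me3. Among all 8645 fasted-only regions the shares were 66.7%, 34.0%, 63.6% and 1.24%, so the first 3 marks were less frequent at the 1119. The median length of the 1119 regions was 1643 bp. The longest H3K27me3 peak of fasted pool 5 spanned 60923 bp on chromosome 11 (96019148 to 96080070). That of fasted pool 2 spanned 36796 bp on chromosome 15 (102754854 to 102791649), which fed pools 1 and 4 covered to 57.1% and 61.9% and fasted pool 5 to 0%, in a list that missed 13.3% of long H3K27me3 regions. Chromosome X held 0.0256% and 0.0144% of the H3K9bhb peaks in the fed and 0.164% and 0.316% in the fasted pools, and its share was below that of every autosome in 27 of the 32 lists. The exceptions were the 4 H3K9me3 lists and the H3K27me3 list of fasted pool 5, with 2.37% on chromosome X. In 17 of the 19 lists with 20 or more chromosome X peaks their median score percentile was under 50, and the longer list of a mark and condition had the higher share in 11 of 16 pairs (exact binomial p = 0.21, two-sided).

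The tests that follow were written down only after their results had been seen, though the deciding rules for lower sensitivity, the shared input and weak regions had been coded before those ran. H3K9bhb lists of fasted crypts held 2.29 times as many peaks as fed lists. Poorer chromatin or a poorer input in both fed pools would lower every mark of those pools alike, but the H4K12bhb ratio from the same pools and inputs was 1.17, lower by 1.12 with a combined SD of 0.65. H3K27ac, H3K27me3, H3K4me3 and H3K9me3 had more peaks in both fasted pools than in both fed pools (ratios 1.71, 3.67, 9.00 and 18.3, the last with an SD of 25.03), so poorer fed pools that touched some marks more than others stay open. Lower sensitivity of the fed H3K9bhb libraries stays open: of regions in both fasted lists, 2.17% of those above the 90th score percentile were in no fed list, against 75.01% of those up to the 25th. The difference may therefore lie largely in weak regions near the calling threshold of the fed lists, and an effect of fasting on H3K9bhb was not separated from this.

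H3K27ac fasted-only calls were enriched at H3K9bhb fasted-only regions. A shared input cannot be the whole cause, since the odds ratios with H3K9bhb and H3K27ac from different pools and inputs were 1.47 (1.41 to 1.54) and 2.64 (2.49 to 2.80). Weak regions of both marks falling below the fed threshold stay open as a cause. Among 15571 regions with both marks in both fasted pools the odds ratio was 6.15, and 2.54 (2.32 to 2.76) across 100 strata of their fasted scores. Stratifying by score lowered the odds ratio but did not remove it. The remainder cannot exclude weak regions as the whole cause, because regions can still differ in strength within a stratum. A joint gain of both marks was not tested. Differences in strength within strata and in how well the fed libraries of both marks performed at the same places were not tested.

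Part of the 95 fed-only H3K9bhb regions may be long peaks lost from the fasted lists during peak calling. The fasted lists missed 10 of 198 regions (5.05%) of 20 kb or more that the 3 other H3K9bhb lists called, against 19 of 3913 (0.486%) of 5 to 10 kb, in length classes chosen after several had been looked at and with regions that could count for both lists. By list these were 3 of 119 (2.52%) against 0.305% in fasted pool 2 and 7 of 79 (8.86%) against 0.667% in fasted pool 5 (two-sided Fisher's exact p = 0.0119 and 5.38e-06, over regions, which are not replicates). The fed lists went the other way, with 0.422% and 0.413% of long regions missing against 14.4% and 24.3%, and of 16 lists of 4 marks 7 missed more of the long regions, 5 with an adjusted p under 0.05, while others such as H4K12bhb of fasted pool 5 missed fewer (0% against 5.15%). Of the 95 regions, 17 (17.9%, Wilson 95% interval 11.5 to 26.8) lay in 4 H3K27ac and H4K12bhb domains of 37126 to 50832 bp, against 11.9% (11.03 to 12.79) of regions called in all 4 libraries and 1.45% (1.21 to 1.72) of fasted-only regions. The other 78 met no such domain of 20 kb or more, so loss within these long domains does not account for them. Loss of shorter H3K9bhb peaks, or of peaks outside such domains, was not tested. A loss of H3K9bhb from these domains on fasting was not tested either.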
